A study of Mus musculus with 18 samples.

How the data were processed

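RNA was measured by sequencing in 18 libraries of mouse forelimb buds, 3 in each of 6 groups. Mutants carried Esco2 alleles flanked by loxP sites (Esco2fl/fl) and the Prrx1-Cre transgene, which is active in limb mesenchyme, and controls carried the same Esco2 alleles without Cre. Mutants and controls were collected at embryonic days 9.5, 10.5 and 11.5 (E9.5, E10.5 and E11.5). Esco2 encodes an acetyltransferase that helps to establish cohesion between sister chromatids during DNA replication. Because the controls lacked Cre, effects of Cre and of Esco2 loss were not separated by this design. The labels describe individual limb buds and RNA selected for a high integrity number, and they do not say whether the libraries of a group came from separate embryos or litters, so all p-values measure only the spread between these libraries.

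The submitters' processing notes name cutadapt (a read trimmer), STAR (an aligner), featureCounts and limma, and the settings of the first, second and last are not given in the sources used here. Per the file headers, the deposited files hold counts from featureCounts 1.6.4, run as reverse-stranded paired-end counting over all exons of each gene in the GENCODE M22 mouse annotation on mm10. By default this leaves out read pairs that align to several places or overlap several genes on the same strand, so genes with such overlaps or near-identical copies are counted low. A second deposited table holds log2 FPKM values that the authors computed for 14692 genes; its normalization is not given in the sources used here, and it served only as an alternative. The counts were used as deposited. Symbols were assigned by gene identifier from the reference annotation, which covered 99.8% of the 55487 identifiers.

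Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out by filterByExpr, which kept 20118 genes, library sizes were scaled by the trimmed mean of M values (TMM), and 1 robust quasi-likelihood model was fitted to all 18 libraries with the 6 groups as coefficients. Mutants were compared with controls at each stage. The mutant effect was compared between stages by interaction contrasts, and control stages were compared with each other. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of each contrast, and the threshold was an adjusted p of 0.05. Fold changes are log2 values given with the standard error of the fit (± SE), and levels are CPM (counts scaled to the TMM-scaled library size), given as mean ± SD of 3 libraries. A rise or a fall means a change past that threshold. The common biological coefficient of variation was 0.231. Totals per library ran from 35034237 to 56230058 counts, and at that depth the spread between libraries, more than counting error, limited the precision of all but the lowest genes.

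There were 27 gene lists with 496 listed genes: p53 targets, apoptosis machinery, cohesin and its regulators, mitosis, DNA replication, DNA damage response, posterior limb and Shh response, anterior limb, proximal limb, distal limb and FGF response, apical ectodermal ridge, thrombospondin and CD47, chondrogenic, hypoxia and glycolysis, integrated stress response, immediate early genes, mitochondrially encoded genes and embryo sex, and markers of surface ectoderm, endothelium, pericytes, erythroid cells, macrophages, platelets, muscle precursors, Schwann cells with neurons, and trunk tissue. Hoxd13 stood in both the posterior and the distal list, and no other gene was listed more than once. Which marker genes limb mesenchyme itself expresses was not analysed here. Each list was tested at each stage with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the 81 tests of lists and stages. Camera compares a list with the other genes. It was repeated with an estimated correlation, and with fry, whose PValue tests whether the genes of a set move on balance one way and whose Mixed value tests whether they change in either direction. Neither of the fry tests compares a set with other genes.

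The genes named were chosen by rule. The rule took Esco2, Trp53, Cdkn1a, Mdm2, Cd47, Fgf8 and Shh at each stage, up to 4 members of each list with the smallest adjusted p, and the 8 largest rises and 8 largest falls among changed genes whose mutant and control libraries did not overlap and whose mean log2 CPM was at least 1. Predicted genes were left out. For interactions and control stages it took the 8 smallest adjusted p-values in each direction under the same filters. Some names were left out for readability, and a few members of the lists are not reported here. The groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. For list counts of 5 or fewer, members outside the rule were named after their values were seen, namely Matn1, Matn4, Tbx2, Kif20a, Bid, Xpc, Sesn1, Ddb2, Wnt5a, Dusp6, Ptch1, Gli1, Sall1, Casp9, Birc2, Hk1, Emcn and mt-Co2; Col2a1 at E11.5 is also outside it. Anpep, Bcl2, Ddx3y, Eng, Esrra, Exo1, Foxc2, Kif11, Meox2, Myh3, Nos1, Nusap1, Pax2, Ptch1, Pvt1, Rrm1, Sox5, Stra6, Top2a, Tubb3, Wwp2 and Xist overlap another annotated gene on the same strand, so read pairs in the shared part were not counted.

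The alternatives were other size factors (RLE and upper quartile), no filter and a filter of 1 CPM in 3 libraries, a fit without robust estimation, a fold threshold of 1.5 by glmTreat, each stage fitted alone, the replicate number as a block, limma-voom with and without the shared first number of the sample codes as a correlation, limma on the authors' log2 FPKM, DESeq2 1.42.0, counts without haemoglobin and mitochondrial genes, and each library left out in turn. Chosen after the data were seen were the removal of a trend of counts with gene length from each library, a fit without both libraries that stood apart, and list tests on the interactions and control stages. No correction for GC content was made. The procedure was tested on simulated data: 3 libraries per group were drawn from the fitted mean and spread of each of 20118 genes, with planted changes. The planted changes were in genes with a mean above 1 CPM in controls. At E10.5 it recovered 23.9% of planted changes of 1.5-fold, 67.2% of 2-fold and 89.4% of 4-fold, with 5 unchanged genes called, and 0 of 20 unchanged lists were called. Genes were drawn independently, so the lists part cannot show how camera with the preset correlation behaves on correlated genes. In the data the estimated correlation of the erythroid list at E10.5 was 0.759. At E9.5 the shares were 19.4%, 67.2% and 92.4%, and for the difference between E11.5 and E10.5 they were 5.97%, 37.3% and 84.8%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Cre controls, protein, tissue sections and cell counts were not analysed here.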

Results

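Gene expression was measured by RNA sequencing in forelimb buds of mouse embryos with Esco2 alleles open to deletion in limb mesenchyme (Esco2fl/fl with Prrx1-Cre, called mutants) and of Esco2fl/fl embryos without Cre (controls). There were 3 mutant and 3 control libraries at each of E9.5, E10.5 and E11.5. Total counts per control library ran from 47740565 to 56230058 at E9.5, from 44992366 to 49489072 at E10.5 and from 35034237 to 41248298 at E11.5. Total counts per mutant library ran from 36390557 to 53505350, from 44402251 to 48147568 and from 38805623 to 50213799 at the same stages. The first principal component of log2 CPM held 40.4% of the variance, the second 15.1% and the third 8.23%.

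**Figure D1:**
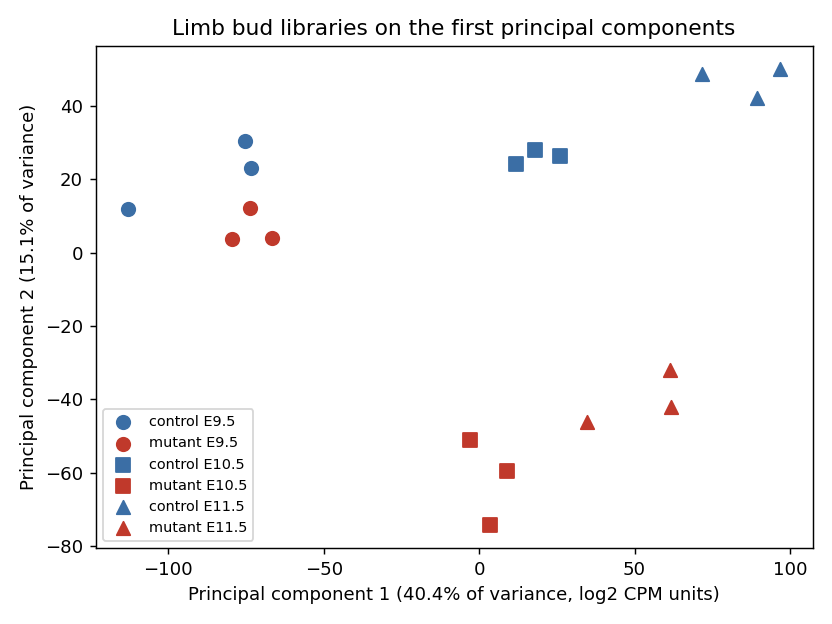
Each point is 1 of the 18 libraries, placed by the first and second principal components of log2 CPM (40.4% and 15.1% of the variance), with colour for genotype and marker shape for stage. The mutants of E10.5 and E11.5 lie below the controls of their stage on the second component.

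A pair of libraries stood apart. In control E9.5 replicate 1, 22294 genes were detected, against 24125 or more in the other libraries, and its mean correlation with the other controls of its stage was the lowest of that group. Gm42418, a gene that overlaps ribosomal RNA sequence, took 1.11% of its counts and at most 0.644% elsewhere. In mutant E10.5 replicate 3, haemoglobin genes took 1.96% of counts, against 0.634% and 0.988% in the other mutants of that stage. Xist, which is transcribed from the inactive X chromosome of females, was at 8.67 CPM in that library and at 0.905 CPM or less in the other 17. Ddx3y, a Y-linked gene, was at 37.2 to 60.2 CPM in all 18 libraries. Each leading count is therefore also given without these libraries, a check chosen after the data were seen.

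Whether Esco2 transcript was lower in mutants was asked first. Esco2 (ENSMUSG00000022034.10, mm10 chromosome 14, 65819038 to 65833994) was at 25.0, 28.1 and 27.2 CPM in the E9.5 controls and at 15.3, 17.8 and 19.8 CPM in the E9.5 mutants. At E10.5 the controls were at 29.4, 33.6 and 28.1 CPM and the mutants at 21.9, 18.9 and 22.3 CPM. At E11.5 the controls were at 30.9, 20.6 and 30.9 CPM and the mutants at 22.5, 23.8 and 22.6 CPM. The log2 change was -0.60 ± 0.14 at E9.5 (adjusted p = 0.162), -0.53 ± 0.14 at E10.5 (adjusted p = 0.0200) and -0.26 ± 0.14 at E11.5 (adjusted p = 0.238). The E10.5 call was lost without control replicate 2 (adjusted p = 0.0967) or without mutant replicate 2 (adjusted p = 0.0936), and at E11.5 the fall passed without control replicate 2 (log2 change -0.42, adjusted p = 0.0382). At E9.5 it passed with DESeq2 and with the length trend removed. These counts sum all exons, so reads outside a deleted part still count, and the limb bud holds cells in which Prrx1-Cre is not active. The values therefore check the deletion only weakly.

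The E9.5 comparison asked what changed at the earliest stage. Cdkn1a (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, rose from 11.2 ± 2.42 to 57.9 ± 4.26 CPM (log2 change 2.38 ± 0.14, n = 3 against 3, adjusted p = 5.87e-08). Mdm2 (ENSMUSG00000020184.15, chromosome 10, 117688875 to 117710758), a p53 target that encodes the ligase acting on p53, rose from 59.6 ± 3.07 to 95.3 ± 6.02 CPM (0.68 ± 0.09, adjusted p = 0.000669). Of 32 measured p53 targets, 9 rose and 0 fell, and 21 rose when adjusted over the list alone. They included Pmaip1, which encodes the death protein Noxa (2.53 ± 0.25, adjusted p = 4.41e-05), and Eda2r, a death receptor gene (2.20 ± 0.31, adjusted p = 0.00155). The list had a median log2 change of 0.50 and passed camera (adjusted p = 3.29e-44, and adjusted p = 0.000269 with an estimated correlation).

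Across 20118 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 37 at E9.5, 36 higher and 1 lower in mutants, and 33 rose at least 2-fold. The largest named rises were those of Inka2, a kinase inhibitor gene (3.60 ± 0.22, adjusted p = 5.87e-08), Ptprv (2.79 ± 0.29, adjusted p = 6.19e-05) and Ddit4l (2.65 ± 0.23, adjusted p = 1.66e-05). The single fall was that of 1500015A07Rik (-2.24 ± 0.32, adjusted p = 0.00206), a gene outside the naming rule, named after its values were seen. Of the 36 genes that rose, 34 also rose at E10.5 and 33 at E11.5, where independence would give 2.63 and 2.89. Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), had a log2 change of -0.08 ± 0.10 (adjusted p = 0.735), and Cd47 of -0.33 ± 0.14 (adjusted p = 0.497). Fgf8 had -0.19 ± 0.33 (adjusted p = 0.823) and Shh -0.55 ± 0.86 (adjusted p = 0.797). Without control E9.5 replicate 2 the count was 76, without control E9.5 replicate 1 it was 38, and without both libraries that stood apart it was 40. With each stage fitted alone it was 7, and DESeq2 called 131. In the fit on the authors' log2 FPKM 34 genes were higher and 5 lower.

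In none of the other 26 lists did a member pass at E9.5 over all genes with edgeR, where 1996 of all genes had an unadjusted p under 0.05. DESeq2, which called 131 genes, called 3 platelet genes and 1 gene each of the endothelial, chondrogenic, muscle precursor and immediate early lists. Adjusted over the list alone in edgeR, 8 of 11 platelet genes and 2 of 25 endothelial genes were higher, as were 1 of 14 immediate early genes and 1 of 18 chondrogenic genes. Camera called 8 further lists at E9.5, and each call was lost with an estimated correlation. These were platelets (median 1.57, adjusted p = 1.40e-09, and adjusted p = 0.205 with an estimated correlation), endothelium (0.25, adjusted p = 4.22e-05, then 0.297), surface ectoderm (0.34, adjusted p = 6.25e-05, then 0.556) and DNA replication (-0.11, adjusted p = 0.00509, then 0.710). The other four were macrophages (adjusted p = 0.0296, then 0.710), the apical ectodermal ridge (0.0370, then 0.651), proximal limb (0.0418, then 0.556) and erythroid cells (0.0460, then 0.839). Leaving out control E9.5 replicate 1 ended the calls of DNA replication (adjusted p = 0.176), proximal limb (0.393) and the ridge (0.0889), and added calls of mitochondrially encoded genes (3.86e-07), mitosis (0.000640), muscle precursors (0.00174), immediate early genes (0.00697) and distal limb (0.0164). Leaving out control E9.5 replicate 2 ended those of proximal limb (0.0652), the ridge (0.116), erythroid cells (0.696) and macrophages (0.473). Without mutant E9.5 replicate 1, DNA replication (0.0695), proximal limb (0.0879), the ridge (0.163) and erythroid cells (0.0747) no longer passed. Without mutant E9.5 replicate 2 proximal limb did not pass (0.107), and without mutant E9.5 replicate 3 erythroid cells (0.0890) did not and the macrophage list turned direction (0.976). Calls were also added for muscle precursors without control E9.5 replicate 2 (0.0226), posterior limb (0.0140) and hypoxia (0.0300) without control E9.5 replicate 3, hypoxia without mutant E9.5 replicate 1 (0.00306), mitosis without mutant E9.5 replicate 2 (0.00428), and pericytes (0.0338) and mitochondrial genes (0.00254) without mutant E9.5 replicate 3. Mitochondrial transcripts took 0.763 ± 0.140% of counts in E9.5 mutants and 0.608 ± 0.0606% in controls, and that list had camera adjusted p = 0.0801 in the main fit (adjusted p = 0.839 with an estimated correlation) and passed with the length trend removed, with limma-voom, with each stage fitted alone and with the replicate number as a block. The chondrogenic list had a median of -0.07 and a mean of 0.21 with the test up (camera adjusted p = 0.384), and the embryo sex list a median of 0.09 and a mean of -0.28 with the test up. The mutant effect also followed gene length across 12611 genes at this stage (Spearman 0.55, genes not being independent replicates). Within this stage, deviations of single libraries from the stage mean correlated with length at -0.63 in control E9.5 replicate 1. The values were 0.53 and 0.21 in the other controls and 0.05, 0.54 and 0.44 in the mutants. Control E9.5 replicate 1 was thus the only library of the stage to run the other way.

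At E10.5, when the limb bud grows out and its skeleton is first laid down, p53 target genes were higher in mutants and cartilage genes lower. Cdkn1a rose from 23.1 ± 2.02 to 185 ± 13.6 CPM (log2 change 3.00 ± 0.14, adjusted p = 1.67e-09), and Ccng1, which encodes cyclin G1, rose by 2.43 ± 0.18 (adjusted p = 2.32e-07). Of the 32 p53 targets 24 rose, and 1, the repair gene Xpc, fell, a call lost in each of the 6 fits without 1 library of that stage; adjusted over the list alone 25 rose and 1 fell. The list median was 0.97 (camera adjusted p = 8.84e-40, and adjusted p = 0.000441 with an estimated correlation). Sox9 (ENSMUSG00000000567.5, chromosome 11, 112782224 to 112787760), the transcription factor that starts cartilage formation, fell from 124 ± 17.6 to 21.6 ± 3.29 CPM (-2.52 ± 0.19, adjusted p = 2.97e-07). Of 18 chondrogenic genes 11 fell, among them Col9a1, which encodes a cartilage collagen (-3.29 ± 0.30, adjusted p = 2.23e-06). Matn1 and Matn4, which encode cartilage matrix proteins, rose, and adjusted over the list alone 12 genes fell and 2 rose. The Matn4 call held in 3 of the 6 fits. The list had a median of -0.93 (camera adjusted p = 1.05e-09, and adjusted p = 0.0296 with an estimated correlation).

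**Figure D2:**
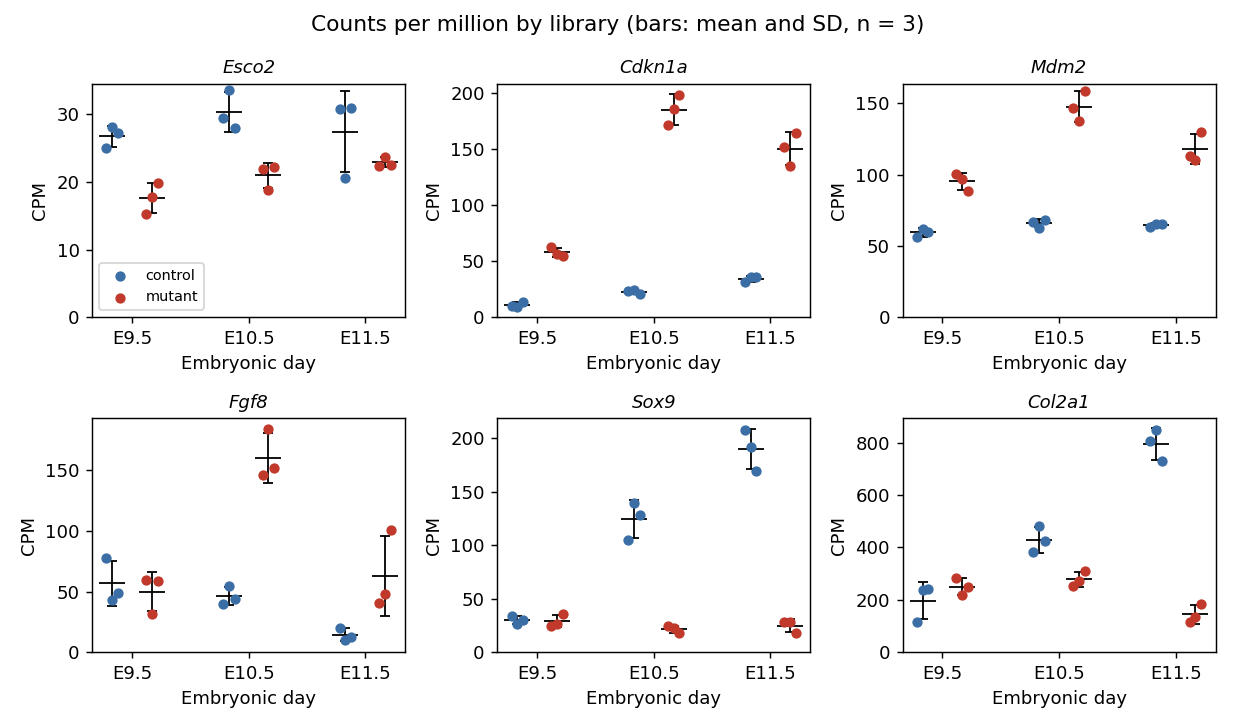
CPM of Esco2, Cdkn1a, Mdm2, Fgf8, Sox9 and Col2a1 in each library by stage and genotype, with 1 point per library and bars for the mean ± SD of 3 libraries. Cdkn1a was higher in each mutant library than in any control library of its stage, with means of 185 against 23.1 CPM at E10.5.

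Genes of the apical ectodermal ridge, the signalling epithelium at the limb tip, were higher in E10.5 mutants. Fgf8 (chromosome 19, 45736798 to 45742915), which encodes the main growth factor of the ridge, rose from 46.2 ± 7.70 to 161 ± 20.6 CPM (1.80 ± 0.34, adjusted p = 0.00207), and Dlx1 rose by 1.62 ± 0.19 (adjusted p = 2.29e-05). In the ridge list 10 of 14 genes rose and 0 fell, also when adjusted over the list alone (median 1.52, camera adjusted p = 1.23e-11, and adjusted p = 0.0462 with an estimated correlation). Among surface ectoderm markers 16 of 19 rose and 0 fell, with 16 higher and 1 lower adjusted over the list alone, including Cldn6, a tight junction gene (1.29 ± 0.19, adjusted p = 0.000217), and Epcam, an epithelial adhesion gene (1.35 ± 0.22, adjusted p = 0.000623). The ectoderm median was 1.06 (camera adjusted p = 1.28e-11), and the call was lost at adjusted p = 0.217 with an estimated correlation. Fewer ectoderm genes, 10, rose without control E10.5 replicate 1, without control E10.5 replicate 3 or without mutant E10.5 replicate 3. Of the FGF response and distal genes, Etv4 (1.01 ± 0.14, adjusted p = 0.000180), Spry1 and Spry4 rose and Cyp26b1, which encodes an enzyme that degrades retinoic acid, fell (-0.99 ± 0.22, adjusted p = 0.00614). That was 3 up and 1 down of 20, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.303). The Spry4 call held in 2 of the 6 fits without 1 library.

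Most of the called genes that pattern the limb along its other axes were lower. Of 11 anterior limb genes 6 fell and 0 rose (8 fell adjusted over the list alone), including the transcription factor gene Alx4 (-1.84 ± 0.26, adjusted p = 0.000175) and Irx5 (-1.40 ± 0.27, adjusted p = 0.00225). The median was -0.89 (camera adjusted p = 1.46e-05, and adjusted p = 0.0838 with an estimated correlation). Of 13 proximal limb genes 5 fell and 0 rose, also adjusted over the list alone, including Tbx18 (-2.60 ± 0.21, adjusted p = 5.97e-07), Shox2, which is needed for the upper arm bone (-1.88 ± 0.19, adjusted p = 6.55e-06), Tbx15 and Pkdcc. The median was -0.65 (camera adjusted p = 1.96e-06, and adjusted p = 0.0838 with an estimated correlation). Proximal falls numbered 3 without control E10.5 replicate 1 or without mutant E10.5 replicate 3, and anterior falls 4 without control E10.5 replicate 2, mutant E10.5 replicate 1 or mutant E10.5 replicate 3. Of 16 posterior and Shh response genes, Osr1 (-1.66 ± 0.21, adjusted p = 5.16e-05), Hand2, Grem1 and Tbx2 fell and 1 gene rose, also adjusted over the list alone. The median was -0.38 (camera adjusted p = 0.0583), and 2 or 3 genes fell in each fit without 1 library. Of these fits the call of Pkdcc held in 4, that of Grem1 in 2 and that of Tbx2 in 1. Shh itself was at 17.9 ± 2.17 CPM in controls and 10.9 ± 1.95 CPM in mutants (-0.72 ± 0.76, adjusted p = 0.583).

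Markers of other cell types moved with the mutant group at E10.5. Of 17 erythroid genes 12 rose and 0 fell (14 adjusted over the list alone), with a median of 1.51 (camera adjusted p = 3.81e-07, and adjusted p = 0.484 with an estimated correlation). Without control E10.5 replicate 1 or without mutant E10.5 replicate 3 edgeR called 0 of them, with 13 and 11 at an unadjusted p under 0.05, and it called 2 without control E10.5 replicate 3. DESeq2 on all libraries called 14. The haemoglobin share of counts was 1.20 ± 0.689% in mutants and 0.420 ± 0.160% in controls. Of 20 macrophage genes 7 rose and 0 fell (9 adjusted over the list alone), including those of complement C1q and the phagocyte gene Cd68 (1.05 ± 0.25, adjusted p = 0.0108, lost without control E10.5 replicate 1 at 0.0587 or replicate 2 at 0.0609). The macrophage median was 1.13 (camera adjusted p = 9.69e-06, and adjusted p = 0.297 with an estimated correlation). Macrophage rises numbered 1, 4 and 3 without control E10.5 replicates 1, 2 and 3 in turn, and 2 without mutant E10.5 replicate 2. Of 25 endothelial genes 7 rose and 2 fell (10 and 2 adjusted over the list alone), with Eng, a receptor gene of vessels, up (1.07 ± 0.12, adjusted p = 2.29e-05) and Esm1, a gene of sprouting vessel tips, down (-2.64 ± 0.46, adjusted p = 0.00108). Endothelial rises numbered 3, 2 and 3 without control E10.5 replicates 1, 2 and 3 in turn and 2 without mutant E10.5 replicate 1 or 2. Camera called that list at adjusted p = 0.0345, lost at adjusted p = 0.704 with an estimated correlation, without control E10.5 replicate 2 (0.0890), mutant E10.5 replicate 1 (0.0646) or mutant E10.5 replicate 2 (0.127).

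Among 12 pericyte and smooth muscle genes Rgs5 rose (1.30 ± 0.27, adjusted p = 0.00380) and Pdgfrb, which encodes a growth factor receptor of mural cells and mesenchyme (-0.89 ± 0.13, adjusted p = 0.000177), Anpep and Cspg4 fell; the list was not called (camera adjusted p = 0.566), and its test pointed down while its median of 0.46 and mean of 0.25 were positive. In the platelet list 0 of 11 genes passed in edgeR or DESeq2, with 2 at an unadjusted p under 0.05 in edgeR (median 0.46, camera adjusted p = 0.228). In the muscle precursor list Lbx1 and Msc rose and Tnnc2 and Myh3 fell of 18 (median -0.27, camera adjusted p = 0.647). Of 14 Schwann cell and neuron genes Tubb3 and Ngfr rose (median 0.42), and of 13 trunk genes Meox2 fell and Pax2 rose. Mitochondrially encoded transcripts took 1.03 ± 0.0463% of counts in mutants and 0.664 ± 0.119% in controls, and 5 of 12 such genes rose (9 adjusted over the list alone; camera adjusted p = 0.000147, and adjusted p = 0.490 with an estimated correlation), among them mt-Co1 (0.67 ± 0.13, adjusted p = 0.00316) and mt-Co2. Of the mitochondrial genes 1 rose without control E10.5 replicate 1 or 2 or mutant E10.5 replicate 1 or 2, and 2 rose without mutant E10.5 replicate 3. Of 14 immediate early genes, which respond to handling of tissue, 4 rose, including Junb (1.57 ± 0.35, adjusted p = 0.00614) and Egr3 (median 1.22, camera adjusted p = 0.000312, and adjusted p = 0.297 with an estimated correlation). In the embryo sex list Xist alone was called (median -0.16 and mean 0.62, test down), and without mutant E10.5 replicate 3 it was not (0.89, adjusted p = 0.563). Of the 6 fits without 1 library, the call of Ngfr held in 4, that of Tnnc2 in 3, those of Cspg4, Myh3 and Xist in 2 and those of Msc and Pax2 in 1, and that of mt-Co2 was lost in each.

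Lists of cell cycle and stress genes were tested as well. Of 28 mitosis genes 5 fell and 0 rose at E10.5 (8 fell adjusted over the list alone), among them Top2a, which encodes a topoisomerase of mitotic chromosomes (-0.64 ± 0.14, adjusted p = 0.00413), and Nusap1 (-0.47 ± 0.09, adjusted p = 0.00175). Kif11, Ttk and Kif20a were the others, and 3 or fewer of the 5 passed in each fit without 1 library. The mitosis median was -0.18 (camera adjusted p = 0.00253, and adjusted p = 0.366 with an estimated correlation). Of 18 cohesin genes Hdac8, which encodes the SMC3 deacetylase (-0.66 ± 0.14, adjusted p = 0.00518), Rad21 and Smc1a fell, and 8 fell adjusted over the list alone (median -0.23, camera adjusted p = 0.00182, and adjusted p = 0.586 with an estimated correlation). Of 29 replication genes Rrm1 fell (median -0.08, camera adjusted p = 0.462). Of 27 DNA damage genes the checkpoint kinase gene Chek2 rose (0.44 ± 0.10, adjusted p = 0.00784, lost without control E10.5 replicate 2 at 0.0504 or mutant E10.5 replicate 3 at 0.0587), while the list as a whole was called lower (median -0.22, camera adjusted p = 0.0267), lost without mutant E10.5 replicate 2 (0.0744) and at adjusted p = 0.756 with an estimated correlation. Of 25 apoptosis genes Dffb, Htra2, Hrk and Bid rose and Bmf was among those that fell, with 1 to 3 rises in each fit without 1 library (median -0.04 and mean 0.10, test up, camera adjusted p = 0.849). Of 17 integrated stress response genes 5 rose and 1 fell, including Atf3 (1.79 ± 0.26, adjusted p = 0.000244) and Psat1, which encodes an enzyme of serine synthesis (0.58 ± 0.11, adjusted p = 0.00157), and 3 rose without control E10.5 replicate 1 or 2 or mutant E10.5 replicate 2 or 3; camera gave adjusted p = 0.0162, lost without control E10.5 replicate 3 (0.0515) and at adjusted p = 0.260 with an estimated correlation. In the thrombospondin and CD47 list Thbs2 (-1.89 ± 0.39, adjusted p = 0.00368) and Nos1 fell and Sirpa rose of 8. Of 25 hypoxia genes Hk2 rose. Adjusted over the list alone, counts higher and lower were 1 and 4 for pericytes, 3 and 4 for muscle, 2 and 0 for Schwann cells and neurons, 1 and 1 for trunk, 5 and 0 for immediate early genes, 5 and 4 for apoptosis, 6 and 1 for the integrated stress response, 2 and 2 for thrombospondin and CD47, 1 and 0 for DNA damage and 0 and 1 for replication. No hypoxia gene passed on that basis. Of the 6 fits without 1 library, the calls of Htra2 and Sirpa held in 3, those of Rrm1 and Hrk in 2 and that of Ttk in 1, and those of Smc1a, Kif11, Kif20a, Bid and Hk2 were lost in each. Cd47 itself had -0.01 ± 0.14 (adjusted p = 0.968).

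Across all genes at E10.5 edgeR called 2802 (13.9% of those tested), 1469 higher and 1333 lower, with 807 up and 444 down at least 2-fold. More were lower than higher with each stage fitted alone (3260 and 3088), without control E10.5 replicate 1 (854 and 772) and without control E10.5 replicate 3 (872 and 857). Large falls included Osr2, a transcription factor gene of joints and palate (31.3 to 1.88 CPM, -4.05 ± 0.37, adjusted p = 2.26e-06), and Wfikkn2 (-3.37 ± 0.47). Large rises included Ptprv (4.88 ± 0.32, adjusted p = 1.06e-07) and Inka2 (4.38 ± 0.22, adjusted p = 2.82e-09). Trp53 had 0.19 ± 0.10 (adjusted p = 0.214), and Mdm2 rose by 1.16 ± 0.09 (adjusted p = 2.97e-07). The count fell to 1626, 1785 and 1729 without control E10.5 replicates 1, 2 and 3 in turn, to 1857 without mutant E10.5 replicate 2 and to 1508 without mutant E10.5 replicate 3, where 1483 of the 2802 genes kept their call. Without both libraries that stood apart it was 3880, with 2480 of the 2802 kept. Among list members, 87 of 160 calls at E10.5 held in each fit without 1 library. Camera also called the posterior list without control E10.5 replicate 3 (0.0356) or mutant E10.5 replicate 2 (0.0375), platelets without mutant E10.5 replicate 1 (0.0305) and Schwann cells and neurons without mutant E10.5 replicate 3 (0.0232). The mutant effect followed gene length with a Spearman correlation of -0.29 across genes.

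At E11.5 the cartilage genes were further below control. Sox9 fell from 190 ± 19.0 to 24.7 ± 6.10 CPM (-2.94 ± 0.19, adjusted p = 1.85e-07), and Col2a1 (ENSMUSG00000022483.17, chromosome 15, 97975602 to 98004695), which encodes the main collagen of cartilage, fell from 794 ± 60.9 to 144 ± 35.7 CPM (-2.46 ± 0.23, adjusted p = 3.39e-06). Col9a2 (-4.34 ± 0.39) and Col9a3 (-3.96 ± 0.32) were among the largest falls of all genes. Of the 18 chondrogenic genes 16 fell and 0 rose, and adjusted over the list alone 16 fell and 1 rose (median -2.40, camera adjusted p = 6.46e-36, and adjusted p = 0.000269 with an estimated correlation). Of the 32 p53 targets 23 rose, including Eda2r (4.22 ± 0.34, adjusted p = 8.92e-07) and Cdkn1a (2.12 ± 0.13, adjusted p = 1.31e-07), and the stress gene Sesn1, whose call held in 3 of the 6 fits without 1 library of that stage, and the repair gene Ddb2 fell. Adjusted over the list alone 25 rose and 2 fell (median 0.81, camera adjusted p = 5.53e-23, and adjusted p = 0.00435 with an estimated correlation). Mdm2 rose by 0.86 ± 0.09 (adjusted p = 6.73e-06). Trp53 rose by 0.35 ± 0.10 (adjusted p = 0.0179), a call lost without control E11.5 replicate 3 (0.28, adjusted p = 0.0936), and Cd47 had -0.26 ± 0.14 (adjusted p = 0.223).

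**Figure D3:**
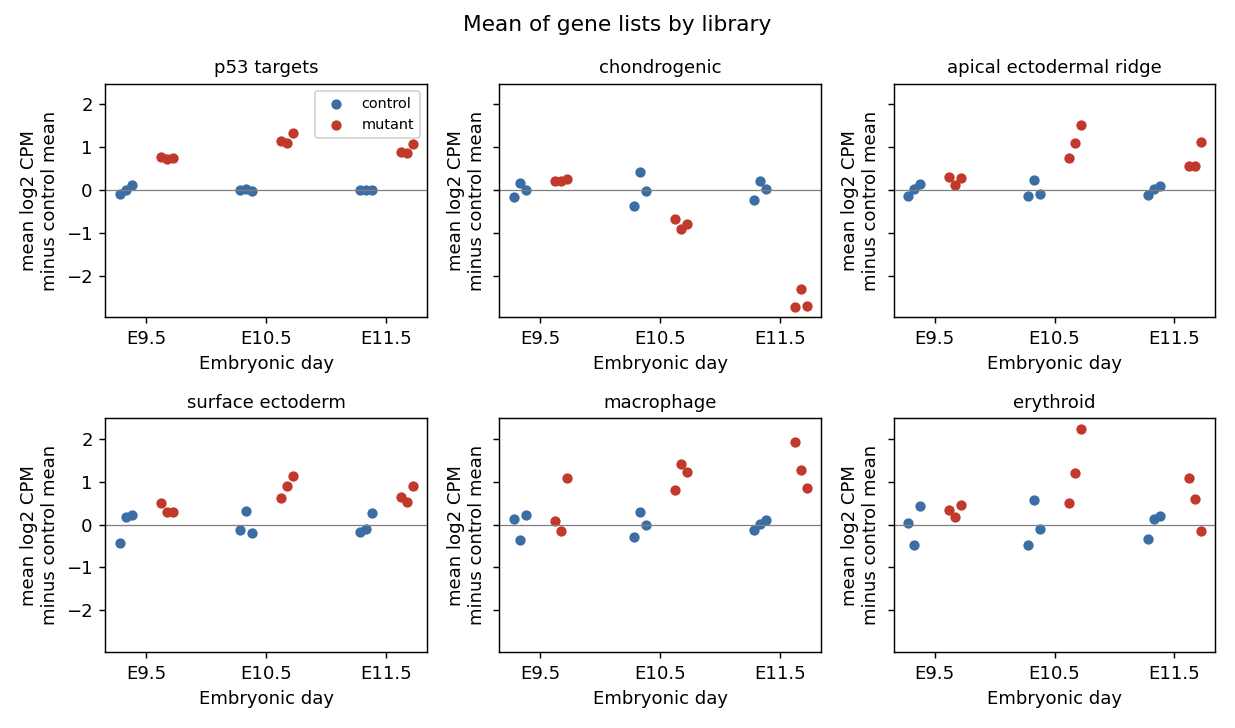
Mean log2 CPM of each list minus the control mean of the same stage, 1 point per library, for p53 targets, chondrogenic genes, the apical ectodermal ridge, surface ectoderm, macrophages and erythroid cells. The medians of single-gene changes at E11.5 were 0.81 for p53 targets and -2.40 for chondrogenic genes.

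In the ridge list 7 of 14 genes rose and 0 fell at E11.5 (8 adjusted over the list alone), including Fgf8 (14.5 ± 5.12 to 63.2 ± 33.0 CPM, 2.12 ± 0.35, adjusted p = 0.000593) and Sp8, a transcription factor gene of the ridge (1.85 ± 0.28, adjusted p = 0.000272). The median was 0.68 (camera adjusted p = 6.42e-06), lost at adjusted p = 0.217 with an estimated correlation. Of 19 surface ectoderm genes 13 rose and 0 fell, 16 and 1 adjusted over the list alone, including Krt19 (1.21 ± 0.22, adjusted p = 0.00131). The median was 0.85 (camera adjusted p = 2.78e-07, and adjusted p = 0.357 with an estimated correlation), and 8 rose without control E11.5 replicate 2 and 6 without mutant E11.5 replicate 3. Of 20 distal and FGF response genes Etv4 (1.27 ± 0.15, adjusted p = 2.10e-05), Etv5, Dusp6, Spry1 and Spry4 rose and Cyp26b1 and Wnt5a fell, 5 and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.487), and 3 rose without mutant E11.5 replicate 3. Of 16 posterior and Shh response genes, the Hedgehog targets Hhip (1.38 ± 0.29, adjusted p = 0.00357), Ptch1 and Gli1 were among those that rose and Osr1 (-2.01 ± 0.21, adjusted p = 9.39e-06), Hand2 and Sall1 fell (4 and 5 adjusted over the list alone; median -0.19, camera adjusted p = 0.558), and 2 rose without control E11.5 replicate 2 or 3 or mutant E11.5 replicate 2 or 3. Shh was at 2.90 ± 3.84 CPM in controls and 3.39 ± 3.62 CPM in mutants (0.22 ± 0.79, adjusted p = 0.883), and it passed without control E11.5 replicate 1 (2.31, adjusted p = 0.0345). Of 11 anterior genes 6 fell, also adjusted over the list alone, including Pax9 (-3.36 ± 0.44, adjusted p = 7.88e-05); the median was -0.88 (camera adjusted p = 0.000647, and adjusted p = 0.205 with an estimated correlation). Of 13 proximal genes Tbx18 (-2.39 ± 0.21, adjusted p = 1.73e-06), Shox2, Tbx15 and Emx2 fell, 5 adjusted over the list alone (median -0.44, camera adjusted p = 0.00128, and adjusted p = 0.260 with an estimated correlation). Of the 6 fits without 1 library, the call of Spry1 held in 5, those of Ptch1, Dusp6 and Wnt5a in 2 and those of Sall1 and Emx2 in 1, and that of Gli1 was lost in each.

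Macrophage markers were higher in E11.5 mutants: 12 of 20 rose and 0 fell, 13 adjusted over the list alone, including Cd68 (1.41 ± 0.26, adjusted p = 0.00119) and C1qb, a complement gene (2.16 ± 0.43, adjusted p = 0.00241). The median was 1.48 (camera adjusted p = 1.84e-07, and adjusted p = 0.258 with an estimated correlation), and 7 rose without control E11.5 replicate 1 and 5 without mutant E11.5 replicate 1. Of the 17 erythroid genes 0 passed at E11.5 in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in edgeR (median 0.52, camera adjusted p = 0.0618), and the haemoglobin share was 0.652 ± 0.278% in mutants and 0.457 ± 0.0893% in controls. The muscle precursor genes Pax3 (5.67 to 41.3 CPM, 2.86 ± 0.31, adjusted p = 1.57e-05), Lbx1 (2.01 ± 0.27, adjusted p = 9.44e-05) and Met rose of 18, 4 adjusted over the list alone (median 0.18, camera adjusted p = 0.0803). Among 12 pericyte genes Rgs5 rose (2.40 ± 0.29, adjusted p = 3.60e-05) and Cspg4 (-1.91 ± 0.29, adjusted p = 0.000256), Anpep and Pdgfrb fell (median -0.16, camera adjusted p = 0.395). Of 25 endothelial genes Eng, Aplnr and Emcn rose and Erg (-1.03 ± 0.22, adjusted p = 0.00329) and Esm1 fell (median -0.01 and mean -0.04, test up, camera adjusted p = 0.996). Of 11 platelet genes Itgb3 fell (median -0.85, camera adjusted p = 0.0627), of 14 Schwann cell and neuron genes Stmn2 fell (median -0.09), and of 13 trunk genes Pax2 and Tcf15 rose and Nkx3-2, Foxc2 and Meox2 fell (median 0.05 and mean -0.14, test down). Of the 6 fits without 1 library, the call of Met held in 5, that of Tcf15 in 4, those of Aplnr and Foxc2 in 3, those of Esm1, Itgb3 and Stmn2 in 2 and that of Emcn in 1.

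Of 29 replication genes 7 were higher and 0 lower at E11.5, 8 adjusted over the list alone, including Ccne1, which encodes cyclin E1 (0.97 ± 0.15, adjusted p = 0.000317), and Rrm2, which encodes a subunit of ribonucleotide reductase (0.64 ± 0.11, adjusted p = 0.000759). The median was 0.16 (camera adjusted p = 0.00320, and adjusted p = 0.704 with an estimated correlation), and 4 rose without control E11.5 replicate 2 or 3 or without mutant E11.5 replicate 2 or 3. Of 28 mitosis genes Mad2l1 and Plk1 rose and Nusap1 fell (camera adjusted p = 0.395), of 27 DNA damage genes Chek2 and Exo1 rose (0.344), and of 18 cohesin genes Hdac8 fell (-0.78 ± 0.14, adjusted p = 0.00137). Of 25 apoptosis genes Cycs, Dffb and Htra2 rose and Bcl2, which protects cells from death (-0.73 ± 0.12, adjusted p = 0.000737), Bmf, Casp9 and Birc2 fell, with 2 or 3 falls in each fit without 1 library (median -0.06 and mean 0.06, test up, camera adjusted p = 0.979). Of 17 integrated stress response genes 6 rose and 1 fell, including Psat1 (0.94 ± 0.11, adjusted p = 2.05e-05) and Atf3 (1.91 ± 0.26, adjusted p = 0.000119); camera gave adjusted p = 0.0162, and adjusted p = 0.260 with an estimated correlation. Of 25 hypoxia and glycolysis genes 6 rose, including the glycolytic genes Eno1 (1.04 ± 0.18, adjusted p = 0.000923) and Hk2 (0.73 ± 0.13, adjusted p = 0.00130), and P4ha2 and Hk1 fell; 3 rose without control E11.5 replicate 3. Of 8 genes of the thrombospondin and CD47 list Cd36 (2.63 ± 0.45, adjusted p = 0.000782) and Sirpa rose and Thbs1 fell. The mitochondrial gene mt-Nd6 rose of 12, with a mitochondrial share of 0.838 ± 0.151% in mutants and 0.692 ± 0.0391% in controls (camera adjusted p = 0.0767). Of 14 immediate early genes Fosl1 rose and Fosb fell (median -0.22 and mean -0.06, test up), and Fosb was higher without control E11.5 replicate 3 (0.53, adjusted p = 0.763). Of 5 embryo sex genes 0 passed in edgeR or DESeq2, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, counts higher and lower were 1 and 3 for pericytes, 3 and 3 for endothelium, 0 and 1 for platelets, 2 and 3 for trunk, 1 and 1 for mitosis, 1 and 0 for DNA damage, 0 and 1 for cohesin, 5 and 6 for apoptosis, 6 and 2 for the integrated stress response, 6 and 2 for hypoxia, 2 and 3 for thrombospondin and CD47 and 1 and 1 for immediate early genes. No mitochondrial gene and no Schwann cell or neuron gene passed on that basis. Of the 6 fits without 1 library, the call of Nusap1 held in 5, that of Thbs1 in 3, those of Htra2, Plk1, Exo1, Fosb and mt-Nd6 in 2 and those of Casp9 and Birc2 in 1, and that of Hk1 was lost in each.

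Across all genes at E11.5 edgeR called 3529 (17.5%), 1613 higher and 1916 lower, with 624 up and 783 down at least 2-fold. With the length trend removed more were higher (2112) than lower (2002), as in the fit on the authors' log2 FPKM (1751 and 1594). Ptprv rose by 4.38 ± 0.31 (adjusted p = 4.13e-07) and Ebf1, a transcription factor gene of mesenchyme, fell (-3.10 ± 0.27). Of genes higher at E10.5, 781 were higher at E11.5 too (independence would give 118), and of those lower 854 were lower (127), while 4 that rose at E10.5 fell at E11.5. The log2 changes of E10.5 and E11.5 correlated across genes at r = 0.57, those of E9.5 and E10.5 at 0.20 and those of E9.5 and E11.5 at 0.10, with no libraries shared and genes not independent. The count was 2252 without control E11.5 replicate 3 and 2213 without mutant E11.5 replicate 3. Without both libraries that stood apart, neither of which is an E11.5 library, it was 5937, with 3520 of the 3529 kept. All groups share 1 estimate of the spread, so libraries of another stage can move this count. Among list members, 100 of 157 calls held in each fit without 1 library. Camera also called platelets without control E11.5 replicate 1 (0.0272) or mutant E11.5 replicate 1 (0.0304). Without control E11.5 replicate 3 it called erythroid cells (0.0290), muscle precursors (0.0311), immediate early genes (0.00242) and mitochondrial genes (0.0450). It called mitochondrial genes without mutant E11.5 replicate 2 (0.0245), and erythroid cells (0.00111) and muscle precursors (0.0158) without mutant E11.5 replicate 3. Gene length correlated with the effect at -0.22.

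Interaction contrasts asked where the mutant effect differed between stages. Sox9 differed between E10.5 and E9.5 (log2 difference -2.46 ± 0.26, adjusted p = 0.000303), since it was at 28.9 CPM in E9.5 mutants and 30.2 CPM in E9.5 controls. Tbx18 differed by -2.51 ± 0.29 (adjusted p = 0.000390) and Pmaip1 by -2.99 ± 0.33 (adjusted p = 0.000372), and the autophagy gene Atg9b by 4.22 ± 0.45 (adjusted p = 0.000303). In all, 446 genes differed, 186 with a higher and 260 with a lower effect at E10.5. Left out in turn, control E9.5 replicates 1 and 2 gave 713 and 2547 genes (for the second 1379 higher and 1168 lower), control E10.5 replicates 1, 2 and 3 gave 190, 165 and 190, mutant E9.5 replicates 1, 2 and 3 gave 295, 185 and 168, and mutant E10.5 replicates 2 and 3 gave 182 and 128. Without both libraries that stood apart the count was 387. Between E11.5 and E9.5, 1291 genes differed, 565 higher and 726 lower, and with the length trend removed 880 were higher and 709 lower. More were higher than lower also with upper-quartile factors, the stricter filter, the authors' log2 FPKM and DESeq2, and without control E9.5 replicate 2 or 3. Col9a3 (-4.26 ± 0.43, adjusted p = 0.000114) and Tbx5, the transcription factor that starts the forelimb (-1.91 ± 0.19, adjusted p = 0.000114), were lower, and Pax3 higher (3.00 ± 0.42, adjusted p = 0.00102). The count was 3395 without control E9.5 replicate 2, 706 and 492 without control E11.5 replicates 2 and 3, 858 and 577 without mutant E9.5 replicates 2 and 3, 613 without mutant E11.5 replicate 3, and 1608 without both libraries that stood apart.

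Between E11.5 and E10.5, 15 genes differed, 14 with a lower effect at E11.5, including the cartilage genes Col9a3 (-2.60 ± 0.42, adjusted p = 0.0303), Col11a2 (-2.48 ± 0.38, adjusted p = 0.0200) and Col2a1 (-1.84 ± 0.31, adjusted p = 0.0402), and Inka2 (-2.08 ± 0.28, adjusted p = 0.0161). The count of 15 was unstable when 1 library was left out, and ran from 0 to 63. The count was 0 without control E10.5 replicate 1 or 3, control E11.5 replicate 2 or mutant E10.5 replicate 3 (1235 to 1461 genes at an unadjusted p under 0.05), and 6 without control E10.5 replicate 2. It was 63 without control E11.5 replicate 1 and 2 without control E11.5 replicate 3. It was 3 without mutant E10.5 replicate 1 or 2, and 8, 7 and 4 without mutant E11.5 replicates 1, 2 and 3. Without mutant E10.5 replicate 3 alone, 0 of the 15 genes kept their call. Without both libraries that stood apart 10 of the 15 kept it, and the count was 18, with 14 lower. With the length trend removed 3 were higher and 12 lower. With the replicate number as a block the count was 8. At an unadjusted p under 0.05 there were 1705 genes, and DESeq2 called 195.

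The control stages were compared as a background of normal development. No first number of a sample code recurs at another stage, so stage and any batch that the codes mark cannot be told apart. From E9.5 to E10.5 Hoxa13, which patterns the hand, rose from 0.153 to 32.7 CPM (7.76 ± 0.44, adjusted p = 6.29e-09), the elastin gene Eln rose by 2.78 ± 0.15 (adjusted p = 6.10e-09), and Lin28a, which encodes an RNA-binding protein of early embryonic cells, fell from 410 to 22.4 CPM (-4.19 ± 0.34, adjusted p = 2.96e-07). From E10.5 to E11.5 Col9a3 rose by 3.08 ± 0.30 (adjusted p = 6.51e-05), Nfia rose by 1.75 ± 0.18 (adjusted p = 8.22e-05), and Lin28a fell to 2.39 CPM (-3.22 ± 0.34, adjusted p = 8.22e-05). From E9.5 to E10.5, 5523 genes changed, 3009 higher and 2514 lower, and with the length trend removed 2633 were higher and 3350 lower. From E10.5 to E11.5, 1910 genes changed, 1328 higher and 582 lower, and in the fit on the authors' log2 FPKM 1067 were higher and 732 lower. With the replicate number as a block it was 191, 157 higher and 34 lower, though the labels give no pairing by that number. The edgeR count of 1910 became 803, 1223 and 970 without control E10.5 replicates 1, 2 and 3 in turn and 1051 and 737 without control E11.5 replicates 2 and 3. Without both libraries that stood apart the counts were 4623 and 3729, though neither is a control of E10.5 or E11.5.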

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

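Of the tests in this part, those on the share of mesenchyme, on blood without 2 libraries and on control E9.5 replicate 1 alone, and the list tests on differences between stages, were chosen only after the results were seen, and the length correction used throughout was added after the data were seen.

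The mutant effect differed between stages. Between E10.5 and E9.5 it differed for 446 genes, and 1 of 60 splits of the labels, the real one, gave as many, with 9 as the highest of the others. Between E11.5 and E9.5 it differed for 1291 genes, and again 1 of 60 splits gave as many, with 65 as the highest other. The other splits shuffled genotype within stages, so they broke up the mutant effect itself along with any difference between stages. They cannot tell a difference between stages from a shared effect, and chance was not excluded by them. Both counts rest on the adjusted p of the interaction contrasts. Between E11.5 and E10.5 the mutant effect differed for 15 genes, 4 of 60 splits gave as many, and the highest other split gave 575. Chance was not excluded there either. The 3 other splits with as many genes gave 71, 464 and 575 and point to a structure of the samples, for which genotype is a candidate: the first took 1 true mutant as mutant at E11.5 and 3 at E10.5, and the other 2 took 0 at E11.5 and 2 at E10.5, so an effect shared by both stages did not cancel in them as it does in the real split. For the comparisons of 3 libraries with 3, the 10 splits cannot give a share under 0.05. The other splits also mixed libraries of both compared groups on each side, so a real effect widened their spread and lowered their counts. Low counts in them are therefore no support for the real split. The real split was 1 of the 10 to give as many genes in each: 37 at E9.5 (highest other 2), 2802 at E10.5 (highest other 1), 3529 at E11.5 (highest other 1), 5523 from E9.5 to E10.5 in controls (highest other 1) and 1910 from E10.5 to E11.5 (highest other 0).

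For E10.5 against E9.5, the genes with the smallest p of the interaction and a higher effect at E10.5 were Atg9b (log2 difference 4.22), Tubb6 (1.53), Baiap2 (0.89), Btbd19 (1.73), Pmm1 (2.12), Man2b1 (0.96), Ass1 (1.89) and Pvt1 (1.84), the last of which overlaps other genes on its strand. Those with a lower effect were Cacna1g (-1.87), Sox9 (-2.46), Pmaip1 (-2.99), Dnm1 (-1.30), Tbx18 (-2.51), Runx1t1 (-2.09), Sox5 (-1.68) and Egflam (-1.60). For E11.5 against E10.5, Stra6 was higher (1.22), and Inka2 (-2.08), Kcnj2 (-1.92), Col11a2 (-2.48), Col9a3 (-2.60), Aqp1 (-2.08), Col2a1 (-1.84), Wwp2 (-0.95) and Ebf1 (-2.07) were lower. For E11.5 against E9.5, Dusp9 (1.27), Atg9b (3.57), Trmt61a (1.13), Pax3 (3.00), Ass1 (2.04), Myc (1.41), Esrra (1.22) and Lpl (0.98) were higher. Lower were Sox9 (-2.88), Tbx5 (-1.91), Col9a3 (-4.26), Eln (-2.0), Cacna1g (-1.76), Dnm1 (-1.37), Gas2 (-1.44) and Col2a1 (-2.81). The chondrogenic list differed at each step, with median log2 differences of -1.17 for E10.5 against E9.5, -1.15 for E11.5 against E10.5 and -2.84 for E11.5 against E9.5 (camera adjusted p = 0.0319, 0.00172 and 0.000706 with an estimated correlation).

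The differences between E9.5 and the later stages could come from control E9.5 replicate 1, or from the opposite trends of the E9.5 and later effects with gene length. Without that library 89.2% of the 1291 genes stayed past the threshold in the same direction, and with the length trend removed from each library 81.6% did. For the 446 genes of E10.5 against E9.5 the shares were 89.7% and 83.2%. Neither therefore accounts for most of the pattern. The 446 calls depended more on mutant E10.5 replicate 3: without it 28.3% were kept, and without both libraries that stood apart 64.6%. A stage-dependent response of the limb bud to Esco2 loss, and an effect of Cre that grows with its activity, stay open as untested, since no Cre control was analysed here.

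The changes at E10.5 and E11.5, with p53 targets higher and cartilage genes lower, ran with a trend on gene length. With that trend removed, 92.4% of the genes changed at E10.5 and 92.4% of those changed at E11.5 stayed past the threshold in the same direction. The E11.5 medians were then 0.79 for p53 targets and -2.29 for chondrogenic genes, which argues against gene length as the source. A delay of the whole limb bud along normal development is a candidate explanation for a part: across 12611 genes the E10.5 effect ran against the control change from E9.5 to E11.5 (Spearman -0.40), and the E11.5 effect against the control change from E9.5 to E10.5 (-0.53), while the E9.5 effect ran with the control change from E10.5 to E11.5 (0.12), with no library shared. A delay does not by itself account for Cdkn1a, which was higher in mutants at all 3 stages and rose with stage in controls (11.2, 23.1 and 34.5 CPM), and a specific effect on cartilage precursors stays open as untested.

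Markers of surface ectoderm, blood and macrophages were higher in mutants at E10.5 or E11.5, as if limb mesenchyme made up less of the tissue. If a lower share of mesenchyme alone raised markers of other cell types alike, ectoderm and endothelium would rise together. The ectoderm score rose above the endothelium score by 0.75 at both E10.5 and E11.5 (two-sided exact permutation p = 0.005 for the sum over both stages, the smallest that the 400 arrangements can give). This pair of lists was chosen after their changes had been seen, so that p restates a known difference. That such markers rise alike was assumed, and which of them limb mesenchyme expresses was not analysed here. A lower share of mesenchyme alone was therefore not excluded. The erythroid rise at E10.5 may come from blood in mutant replicate 3 alone, since without that library 0 of 17 erythroid genes passed in edgeR. But 11 still had an unadjusted p under 0.05, and the median was 0.89. Without control E10.5 replicate 1, with mutant replicate 3 kept, 0 passed too. The haemoglobin share was 0.634%, 0.988% and 1.96% in the E10.5 mutants and 0.294%, 0.600% and 0.365% in the E10.5 controls. Without mutant replicate 3 and control E9.5 replicate 1 together 2 genes passed, though the latter is not an E10.5 library. The rule written before this test took fewer than 2 passing genes as a sign of blood in that library alone. It was set aside after the values were seen. Blood in 1 mutant and blood in all 3 cannot be told apart with so few libraries. Loss of mesenchymal cells, more macrophages in the tissue and dissection of the buds stay open, as no cell counts were analysed here.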

How the results depend on the processing

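The length correction, the fit without both libraries that stood apart, and the list tests on differences between stages were added after the data were seen. With RLE or upper-quartile factors, no filter, the stricter filter, and without haemoglobin and mitochondrial genes, each count of changed genes stayed within 1.5 times its reported value, and scaling moved the median of all genes by less than 0.1. Named gene results were chosen mostly for a small p or a large change in these same data. They include Esco2, Trp53, Cd47, Shh and Fgf8 also where these did not pass. Of 291 such results, 291 kept their side of the threshold with RLE factors, 280 with limma-voom, 282 with limma-voom and a correlation of 0.299 within the first number of the sample codes, 282 with the length trend removed, 277 without both libraries that stood apart, 272 with the replicate number as a block, 266 with no filter and 176 with the fold threshold of 1.5. With each stage alone it was 197 of 218. For limma on the authors' log2 FPKM it was 274 of 286, and for DESeq2 287 of 289. Of 81 list tests, 81 did with RLE factors, 75 with limma-voom, 74 with the authors' log2 FPKM, 73 with fry, 76 with the length trend removed, 72 without both libraries that stood apart, 71 with each stage alone and 54 with an estimated correlation. With 1 library left out, 442 of 486 list tests and 1739 of 1992 named gene tests did.

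At E9.5 the count was 7 with each stage fitted alone and 131 with DESeq2. At E10.5 it was 6348 with each stage alone. The fold threshold of 1.5, which asks for larger changes, gave 602 genes at E10.5, 671 at E11.5, 50, 3 and 100 for the differences of E10.5 from E9.5, E11.5 from E10.5 and E11.5 from E9.5, and 1316 and 456 for the control stages. DESeq2 gave 1417, 195 and 2588 for those differences. For E11.5 against E10.5 the count was 9 without robust estimation, 7 with limma-voom and 9 with the authors' log2 FPKM. Without both libraries that stood apart it was 5937 at E11.5 and 3729 for controls from E10.5 to E11.5, though neither library is in those comparisons. All 6 groups share 1 estimate of the spread. Without control E9.5 replicate 1 alone, 3520 of the 3529 E11.5 calls were kept, and without mutant E10.5 replicate 3 alone 3268 were. Camera with an estimated correlation called 6 of the 81 list tests, against 33 reported. The replicate number as a block gave 8 genes for E11.5 against E10.5 and 191 for controls from E10.5 to E11.5. The labels give no pairing by that number. Of 18 libraries, 10 correlated best with the library of their own number, out of 3 candidates each. Correlations of all same-number pairs, best or not, ran from -0.15 to 0.18. These values neither show nor exclude a pairing. Apart from the fold threshold, the cause of these shifts was not tested.

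Leaving out 1 library of the groups that a contrast compares gave 30 to 76 genes at E9.5, 1508 to 2259 at E10.5 and 2213 to 2948 at E11.5. It gave 128 to 2547, 0 to 63 and 492 to 3395 for the differences of E10.5 from E9.5, E11.5 from E10.5 and E11.5 from E9.5, and 3687 to 6985 and 737 to 1919 for the control stages. In the 4 fits with 0 genes, edgeR had 1235 to 1461 at an unadjusted p under 0.05. The macrophage list at E9.5 reversed without mutant E9.5 replicate 3 (adjusted p = 0.976), with a range of 6.40e-05 to 0.976 over the libraries left out. Fosb at E11.5 reversed without control E11.5 replicate 3 (log2 change 0.53, adjusted p = 0.763), with a range of -4.38 to 0.53. With 2 libraries in a group, these fits assume that they vary like the other groups. List tests were not run with DESeq2, a fold threshold or the correlation within sample codes. In simulated data, 67.2% of planted 2-fold changes in genes above 1 CPM were recovered at E10.5. For differences between stages the share was lower, with 38.8% recovered for E11.5 against E9.5. Far fewer genes changed in the simulation, where 125 were called at E10.5 against 2802 in the data, so its adjusted threshold was stricter. These shares set no limit for the data. Of the 2802 calls, only 807 rises and 444 falls were at least 2-fold.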

Other observations

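The list tests in this part were chosen only after the results were seen, and changes between control stages cannot be told apart from any batch that the sample codes mark. In controls, genes of the posterior limb and the Shh response rose together from E9.5 to E10.5: 14 of 16 rose and 0 fell, with a median log2 change of 2.65 (camera adjusted p = 7.62e-25, and adjusted p = 0.00168 with an estimated correlation). Of the cartilage genes 11 of 18 were higher and 0 lower from E9.5 to E10.5 (median 1.22, adjusted p = 0.162 with an estimated correlation) and 14 higher and 1 lower from E10.5 to E11.5 (median 1.55, adjusted p = 0.00171 with an estimated correlation). Muscle precursor and muscle genes rose as well, 14 of 18 in the earlier and 12 in the later step (adjusted p = 0.209 and 0.286 with an estimated correlation), and 14 of 20 macrophage genes rose in the earlier step (adjusted p = 0.209 with an estimated correlation). Of the replication genes 9 of 29 were lower from E9.5 to E10.5 and 8 from E10.5 to E11.5, and the list was not called with an estimated correlation (adjusted p = 0.645 and 0.383). In the earlier step 13 of 25 hypoxia and glycolysis genes were lower and 2 higher (adjusted p = 0.395 with an estimated correlation).

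The mutant effect on 4 named genes differed between E9.5 and a later stage. Pmaip1, the gene of the death protein Noxa, was at 1.44 ± 0.372 CPM (SD, n = 3) in E9.5 controls and 8.31 ± 1.5 CPM in E9.5 mutants, and at 52.6 ± 11 and 38.4 ± 3.05 CPM at E10.5, so it rose in controls by 5.20 ± 0.27 on the log2 scale (adjusted p = 2.88e-09), and the mutant effect differed between those stages by -2.99 (adjusted p = 0.000372). Lin28a declined in both genotypes, from 410 ± 17.5 to 22.4 ± 5.39 and 2.39 ± 1.07 CPM in controls and from 427 ± 68.9 to 68.4 ± 2.88 and 16.6 ± 9.57 CPM in mutants, with an effect that differed by 2.72 between E11.5 and E9.5 (adjusted p = 0.00298). Pax3, a gene of muscle precursors, was at 26.3 ± 5.15 and 5.67 ± 3.14 CPM in controls at E10.5 and E11.5 and at 47.3 ± 5.46 and 41.3 ± 6.04 CPM in mutants, and its effect differed between E11.5 and E9.5 (3.00, adjusted p = 0.00102) but not past the threshold between E11.5 and E10.5 (2.01, adjusted p = 0.104). Osr2 was at 31.3 ± 7.84 and 36.1 ± 1.51 CPM in controls and at 1.88 ± 0.631 and 11.3 ± 5.30 CPM in mutants at those stages, and its effect differed between E10.5 and E9.5 (-3.94, adjusted p = 0.000858) but not past the threshold between E11.5 and E10.5 (2.38, adjusted p = 0.0871).

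The embryo sex genes gave an unexplained library. Ddx3y was at 37.2 to 60.2 CPM in all 18 libraries, and Xist had 423 counts in mutant E10.5 replicate 3 (8.67 CPM) and at most 0.905 CPM elsewhere. Its Y-linked level was within the range of the other libraries, and no cause was tested.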
